A study of Arabidopsis thaliana with 12 samples.

How the data were processed

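RNA sequencing counts of Arabidopsis thaliana seedlings, 10 days old, were analysed from 12 libraries in 2 experiments. In the first experiment wild type and the cerk1 mutant were treated with sterile water (mock) or with 100 nM flg22, a peptide of bacterial flagellin, and each of the 4 combinations had 1 library. In the second, cerk1 plants carrying a FLAG-tagged CERK1 transgene under the CERK1 promoter were left untreated, and each of 4 lines, named here CERK1_WT, CERK1_3A, CERK1_3D and CERK1_3E after the transgene, had 2 libraries. Groups came from the sample titles. The library titled cerk1 with flg22 carries the genotype cerk2-/- in another label and was taken as cerk1 from its title. The labels give neither the duration of the flg22 treatment, nor the substituted residues, nor how many independent transformants stand behind a construct, so construct and line could not be separated. Nothing in the labels says that the libraries of a line came from separate cultures, so p values measure only the spread between these samples, which may be technical.

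The deposited tables hold whole-number counts of reads or fragments per gene, and the authors applied no normalization to them. Reads had been placed on the TAIR10 build per the submitters' processing notes. The aligner, the counting tool, the strand setting and the filters were not given in the sources used here. Both tables include transcribed loci outside the annotation, named newGene: 208 of the 21981 entries in the flg22 experiment and 246 of the 27612 entries in the lines. Of the 21773 annotated genes in both tables, 52.1% had the same stated length, so the tables rest on different gene models and no level was compared between them. Library totals were 18159354 to 22663236 counts in the flg22 experiment and 36013439 to 41288819 in the lines. All 12 sample columns were used. Gene symbols came from a TAIR10.1 annotation, which served for names and for gene order only, and no coordinates are given.

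For the flg22 experiment, counts were divided by library totals scaled with TMM factors and expressed as CPM in edgeR 4.0.16 under R 4.3.3. Genes with a CPM of at least 1 in at least 1 library were kept, 18872 in number. Ratios were formed on CPM + 1, and a gene was counted as different at 4-fold or more. With 1 library per combination no p value was computed for any gene. Ratios of single genes are count ratios without the added 1, with a 95% exact binomial interval. A ratio against a library with 0 counts was computed against a floor of 3 counts in that library and is a lower bound. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

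For the lines, edgeR's quasi-likelihood test was run on all 8 libraries with group as the only term, TMM factors and the filterByExpr filter, which kept 21274 genes. All 6 comparisons between lines were tested, two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. The fit had 4 residual degrees of freedom and a common biological coefficient of variation of 0.170. Errors of levels are SD over 2 libraries, and errors of log2 fold changes are SE. Sets of genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. The libraries of a line correlated across genes with r of 0.974 to 0.981 on log2 CPM, and libraries of different lines with 0.973 to 0.983. No pair of libraries of a line agreed within sampling noise. The libraries of CERK1_3D were furthest apart, by at least 2-fold for 750 genes. The number was 381 in CERK1_WT, 355 in CERK1_3A and 388 in CERK1_3E. Replicate numbers did not pair libraries across lines: the correlation across genes of replicate differences between lines lay between -0.04 and 0.15, so a replicate block was used only as an alternative.

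The tests, thresholds, gene lists, named-gene rule and alternatives were fixed before the data were examined, apart from 2 alternatives added afterwards. The 19 gene lists held 442 entries, of which 1 was dropped because its locus and symbol disagreed. They covered immediate early immunity markers, WRKY factors, pattern receptors and their signalling, salicylic acid, jasmonate, ethylene, indolic compounds and camalexin, phenylpropanoids and lignin, flavonoids and anthocyanins, photosynthesis, auxin, cell cycle, circadian clock, heat shock, endoplasmic reticulum folding, iron deficiency, phosphate starvation, root cell types and seed maturation. Of the 12 seed maturation genes 2 were measured in the lines and 0 in the flg22 experiment, so 18 lists were tested. In the flg22 experiment the median log2 ratio of a list was placed among those of 10000 random lists of the same size, matched on expression in 20 bins, and called outside their range below the 2.5 or above the 97.5 percentile. In the lines, p values of lists were adjusted over the 18 lists of a comparison, and members were also adjusted over the list alone. The flg22-raised and flg22-lowered sets were the genes at least 4-fold higher or lower in WT_flg22 than in WT_mock, so they were chosen on other libraries than those they were tested in.

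Named genes were CERK1 first. For each variant against CERK1_WT they were up to 5 rises and 5 falls with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between libraries, plus the 2 members of each list with the smallest adjusted p. Between variants up to 3 rises and 3 falls were taken by the same rule. In the flg22 experiment, among genes with at least 50 counts summed over the libraries compared, they were the 6 largest rises and falls in wild type, the 5 largest each way for cerk1_mock against WT_mock and for the difference of responses, and the 2 members of each list with the largest ratio in wild type. Other genes are named as chosen after their values were seen. Results for 1 gene are not reported here, although it stays in the counts of calls.

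The procedure was checked on simulated data. With 200 changed genes planted per comparison of lines, 62% to 68% of 2-fold changes and 92% to 97% of 4-fold changes were called, and 7 to 18 of 165 to 183 calls were false. So many planted genes loosen the adjusted threshold, and the counts were drawn from the fitted spread. These rates therefore do not carry over to the real comparisons, in which 1 to 6 genes were called. Among 20 sets without a planted change, camera gave an unadjusted p under 0.05 for 0 to 2. Genes were drawn independently there, while members of some real lists moved together. For jasmonate genes the estimated correlation was 0.41 in CERK1_3A against CERK1_WT. The check therefore cannot show whether the preset correlation suits such lists. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, other low-count filters, the 4 libraries compared alone, the replicate block, the fold threshold, leaving out organelle genes or each library in turn, other set definitions, and for the flg22 experiment other pseudocounts, scalings, filters and a 2-fold size.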

Results

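Transcript levels were measured by RNA sequencing in whole Arabidopsis seedlings. The first experiment compared wild type with the cerk1 mutant, each mock-treated or treated with 100 nM flg22, at 1 library per combination. CERK1 is the LysM receptor kinase through which Arabidopsis perceives chitin, whereas flg22, a peptide of bacterial flagellin, is perceived by the receptor kinase FLS2. Totals were 18565607 counts in WT_mock, 22663236 in WT_flg22, 18159354 in cerk1_mock and 20491446 in cerk1_flg22. The second experiment compared untreated cerk1 seedlings carrying a CERK1-FLAG transgene of wild-type sequence (CERK1_WT) or 1 of 3 mutated forms (CERK1_3A, CERK1_3D, CERK1_3E), with 2 libraries per line and 36013439 to 41288819 counts per library. The series title refers to phosphorylation of CERK1 that flg22 induces. The comparisons therefore asked whether the transcriptional response to flg22 differed without CERK1, and whether the mutated forms changed the untreated transcriptome.

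In wild type, flg22 went with a broad induction of defence genes. AT1G26380, a FAD-linked oxidoreductase of pathogen-induced indole metabolism, stood at 0.252 CPM in WT_mock and 987 CPM in WT_flg22. IGMT2, an indole glucosinolate methyltransferase, was 821-fold higher (95% counting interval 556 to 1269), and BCB, a blue copper-binding protein, 535-fold higher (353 to 853). The lectin-related genes PP2-B13 and PP2-B14 reached 515 and 412 CPM from 0.101 and 0.302 CPM, and the cytochrome P450 gene CYP82C3 reached 339 CPM from 0.0504 CPM. IGMT2, PP2-B13 and PP2-B14 have close relatives in tandem. For none of the genes named here could the assignment of reads between similar genes be checked. Of 18872 genes, 1186 were at least 4-fold higher and 89 at least 4-fold lower in WT_flg22, against 6 and 102 between the mock libraries of the 2 genotypes. The largest decreases included CYP81D11, a xenobiotic-responsive cytochrome P450, at 53.5 and 0.851 CPM (62.8-fold lower, 39.1 to 108), the aldo-keto reductase gene ChlAKR (45.8-fold lower, 20.8 to 126) and the acid phosphatase gene PAP17, induced by phosphate starvation (12.4-fold lower, 10.5 to 14.7). AT3G19430 and AT1G75960 were 56.4-fold and 17.1-fold lower, and AT1G52070 went from 52.6 to 2.95 CPM. With flg22 in cerk1, AT3G19430 and AT1G52070 were instead higher, 10.4-fold (4.82 to 26.9) and 17.1-fold (11.9 to 25.2). These ratios rest on 1 library per group and carry no replicate error.

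Among the fixed gene lists, those of immunity genes had the largest increases with flg22. Of the 30 measured immediate early immunity genes 29 were at least 2-fold higher in WT_flg22, with a median log2 ratio of 4.87. Examples were CYP81F2, an indole glucosinolate hydroxylase, 323-fold higher (261 to 406), and the receptor-like kinase gene FRK1, a standard flg22 marker, 576-fold higher (197 to 2797) from 3 counts in WT_mock. Among 23 defence WRKY transcription factors 18 were at least 2-fold higher (median 3.49), with WRKY40 204-fold higher (139 to 313). Of 30 pattern receptor and signalling genes 23 were at least 2-fold higher and 2 lower (median 2.55), among them FLS2 itself at 6.0-fold (5.53 to 6.51), its co-receptor BAK1 at 6.34-fold (5.99 to 6.73) and the chitin receptor LYK5 at 15.4-fold (12 to 20). Indolic and camalexin synthesis (20 of 27 genes, median 2.39) and salicylic acid genes (17 of 30, median 1.5) were higher, with the camalexin enzyme PAD3 64.9-fold (44.4 to 98.7) and the regulator CBP60G 72.7-fold higher (51.4 to 107). Medians were smaller for ethylene (0.88, 9 of 19 genes), phenylpropanoid (0.57, 5 of 16) and jasmonate genes (0.50, 9 of 25), although LOX4, a lipoxygenase of jasmonate synthesis, was 121-fold higher (95.3 to 157). FRK1, FLS2, BAK1, LYK5 and PAD3 were chosen after their values were seen. Phosphate starvation genes (median -0.90, 6 of 14 at least 2-fold lower), cell cycle genes (-0.59, 0 of 24), root markers (-0.48, 3 of 21) and flavonoid genes (-0.45, 4 of 13) were lower. These 12 lists lay outside the range of random lists. Medians of auxin (0.15), photosynthesis (-0.04), clock (-0.04), heat shock (-0.00), endoplasmic reticulum folding (-0.17) and iron deficiency genes (-0.07) did not. The median of all genes was -0.03 in wild type and -0.01 in cerk1, and with scaling by library total in place of TMM it was -0.28 and -0.17, so list values depend on the scaling by about that shift.

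The cerk1 seedlings showed nearly the same set of flg22-raised genes. Of the 1186 genes raised at least 4-fold in wild type, 1067 (90.0%) were raised at least 4-fold and 1184 at least 2-fold in cerk1, and their median log2 ratio was 2.98 in wild type and 3.03 in cerk1. In cerk1, 1287 genes were at least 4-fold higher and 88 at least 4-fold lower with flg22. AT1G26380 reached 820 CPM, CYP81F2 was 428-fold higher (314 to 599), FLS2 6.15-fold (5.61 to 6.75), BAK1 7.02-fold (6.58 to 7.49) and WRKY40 431-fold (252 to 810). The responses of the 2 genotypes correlated across genes, which are not independent replicates, with Pearson's r of 0.90 and Spearman's rho of 0.77. Of the 89 genes at least 4-fold lower in wild type, 43 were so in cerk1 and 64 were at least 2-fold lower. The medians of immediate early (5.21), WRKY (3.89), receptor (2.63), indolic (2.68), salicylic acid (2.18), jasmonate (1.64), ethylene (1.12) and phenylpropanoid genes (0.93) lay above those of random lists, and those of phosphate starvation (-1.14) and cell cycle genes (-0.53) below. The other medians in cerk1 were 0.30 for root markers, 0.23 for auxin, 0.12 for heat shock, 0.09 for iron deficiency, 0.04 for endoplasmic reticulum folding, -0.19 for clock, -0.25 for flavonoid and -0.27 for photosynthesis genes. CERK1 itself was measured at 24.9 CPM in WT_mock, 273 in WT_flg22, 9.70 in cerk1_mock and 119 in cerk1_flg22, so its transcript was 11-fold higher with flg22 in wild type (10.0 to 12.1) and 12.3-fold in cerk1 (10.6 to 14.3). The transcript in cerk1 was 0.390 times that of wild type without flg22 (0.329 to 0.462) and 0.436 times with it (0.415 to 0.458).

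**Figure D1:**
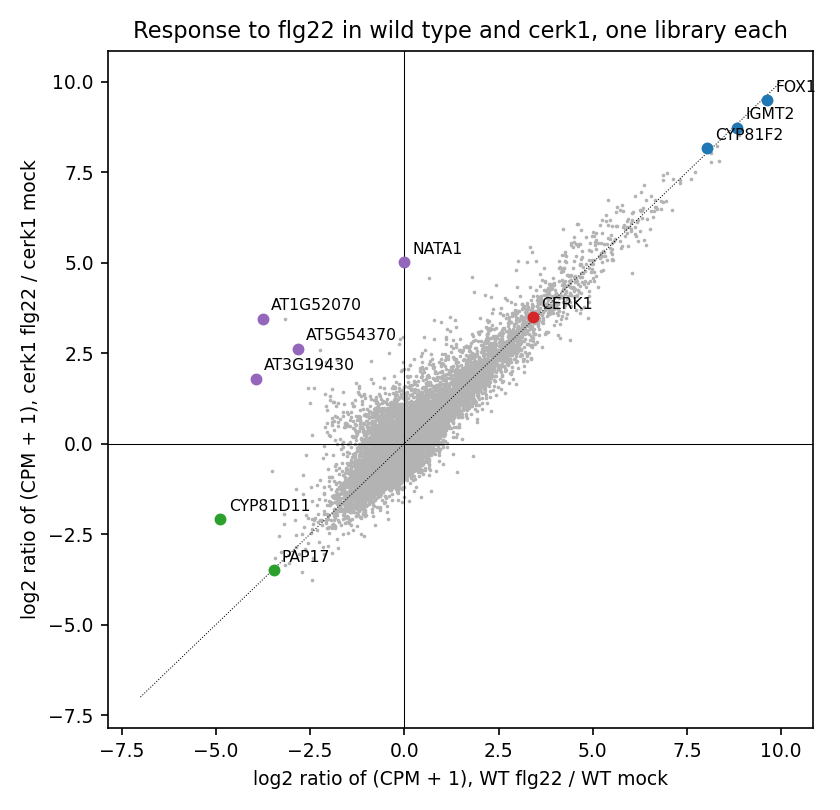
Each point is 1 of 18872 genes, with the log2 ratio of CPM + 1 between flg22 and mock in wild type on the horizontal axis and in cerk1 on the vertical axis, and the dotted line marks equal responses; FOX1 is AT1G26380. Most raised genes lie near the line (r = 0.90 across genes), and AT1G52070, AT3G19430 and AT5G54370 lie to the left of zero in wild type and above zero in cerk1.

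Without flg22, 756 genes were at least 2-fold lower in the cerk1 library than in wild type and 57 at least 2-fold higher. Root markers and several single genes were among those lower. AT3G22142, a protein of the protease inhibitor and lipid transfer family, stood at 223 CPM in WT_mock and 2.41 CPM in cerk1_mock (92.3-fold lower, 69.5 to 125), and HRGP1, a cell wall hydroxyproline-rich glycoprotein, at 120 and 2.51 CPM (47.7-fold lower, 36.1 to 64.5). The beta-glucosidase genes BGLU34 and BGLU35, which are close in sequence, had 526 and 432 counts in WT_mock and 1 and 0 in cerk1_mock, for BGLU35 at least 144-fold lower. AT1G52060, a lectin gene next to AT1G52070, had 428 counts in WT_mock and 1 in cerk1_mock. Of the 21 root markers 11 were at least 2-fold lower (median -1.04), among them the root-hair oxidase gene RHD2 at 13.8 and 2.66 CPM and the expansin gene EXPA7 at 9.93 and 1.26 CPM, both chosen after their values were seen. The medians of phosphate starvation (-0.56), phenylpropanoid (-0.54), flavonoid (-0.38), receptor (-0.37), indolic (-0.36), jasmonate (-0.31) and ethylene genes (-0.26) also lay below random lists, and no list lay above. Higher in cerk1_mock were HEI10, a meiotic crossover gene, at 2.32 and 36.1 CPM (15.6-fold, 11.6 to 21.5), its overlapping opposite-strand neighbour MRD1 (at least 20.3-fold), AT1G56660 (6.89-fold, 4.43 to 11.2), the plastid gene ATCG00210 (24.3-fold, 10.1 to 76.3) and the unannotated locus Arab_newGene_59 (at least 29.9-fold). HEI10 was also at 37.2 CPM in cerk1_flg22 and 2.95 CPM in WT_flg22, and MRD1 had 32 and 2 counts there, so these 2 genes differed between the genotypes in both treatments. AT1G56660 was likewise higher in cerk1_flg22 than in WT_flg22 (1.85-fold, 1.63 to 2.11). Of the genes named as lower, AT3G22142, HRGP1, BGLU34 and BGLU35 stayed lower, at 0.242, 0.209, 0.228 and 0.260 times WT_flg22. AT1G52060 was 6.97-fold higher there. Where the flg22 libraries did not differ in the same direction, as for AT1G52070, nothing here separates genotype from growth or dissection of the sample.

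The flg22 response differed at least 4-fold between genotypes for 115 genes, and the log2 difference, cerk1 minus wild type, was positive for 112 and negative for 3. These counts depend on the value added before the ratio: 24 genes passed with CPM + 5 and 407 with CPM + 0.1, and between the mock libraries 31 and 351 in place of 108. A positive difference is not always a larger response, since 74 of the 112 genes were at least 2-fold lower with flg22 in wild type. The number at least 2-fold higher with flg22 in cerk1 was also 74 of the 112. CYP81D11, with log2 ratios of -4.88 in wild type and -2.08 in cerk1, and ChlAKR, with -3.50 and -0.75, fell less in cerk1. The largest differences on the log2 scale were 7.21 for AT1G52070, 6.62 for AT1G52060, 5.73 for AT3G19430 and 5.45 for AT5G54370, the first 2 encoding mannose-binding lectin proteins and the others proteins related to late embryogenesis abundant proteins. AT1G52070, for example, had 52.6 CPM in WT_mock, 2.95 in WT_flg22, 1.61 in cerk1_mock and 27.4 in cerk1_flg22. NATA1, a jasmonate-inducible acetyltransferase, had 619 counts in cerk1_flg22 and 0 in the other 3 libraries, at least 207-fold above WT_flg22. The largest negative differences were -2.19 for Arab_newGene_59, -2.17 for the transcription factor gene ASIL1, -2.03 for ATCG00210, -1.71 for AT2G27800 and -1.66 for AT2G36980. Of the 112 genes, 44 were among the 102 that were lower in cerk1_mock. That overlap is partly built in, since both measures use the 2 mock libraries. Compared directly, the 2 flg22 libraries differed at least 4-fold for 24 genes, 17 of them higher in cerk1_flg22. That direct comparison was chosen after seeing the data, and so was a count of the mock libraries without the genes at least 4-fold lower with flg22 in wild type, which left 98 of 108 genes. The lists with the largest median difference of responses were root markers (0.88, 6 of 21 genes at least 2-fold) and jasmonate genes (0.55, 9 of 25). None of these differences could be tested without replicates.

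**Figure D2:**
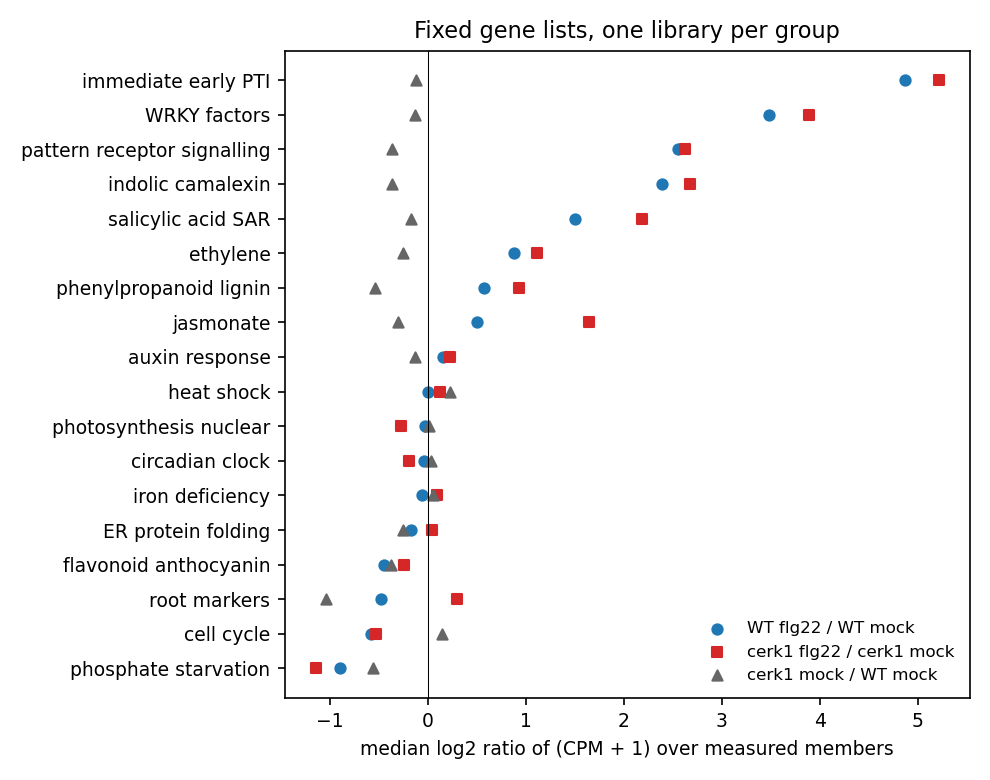
The horizontal axis gives the median log2 ratio of CPM + 1 over the measured genes of each of 18 fixed lists, for flg22 against mock in wild type (circles) and in cerk1 (squares) and for cerk1 against wild type without flg22 (triangles), with 1 library per group. Immediate early immunity genes reach 4.87 and 5.21 with flg22, and root markers lie at -1.04 in the untreated mutant.

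In the complementation lines, CERK1 transcript was most abundant in the 3D and 3E lines. It was measured at 56.8 ± 6.1 CPM in CERK1_WT, 76.7 ± 4.8 in CERK1_3A, 118 ± 4.2 in CERK1_3D and 121 ± 11 in CERK1_3E (SD, n = 2), counting endogenous and transgene transcripts together. The stated length of CERK1 was 5982 in the lines and 2063 in the flg22 experiment. Its counts in the lines may therefore take in neighbouring sequence, which could not be checked. CERK1 rose in CERK1_3D relative to CERK1_WT by 1.05 on the log2 scale (SE 0.11, adjusted p = 0.0451 by edgeR, higher in 2 of 2 libraries). In CERK1_3E the difference was 1.1 (SE 0.11, 2 of 2 libraries) with an adjusted p of 0.0592, and in CERK1_3A it was 0.43 (adjusted p = 1.0). DESeq2 called it in CERK1_3E as well (adjusted p = 5.06e-14). The CERK1_3D call was lost with the replicate block (log2 1.05, adjusted p = 0.0589), with only the 4 libraries compared, at a mean CPM of at least 5 and without organelle genes. It was also lost when 1 library was left out, with adjusted p values of 0.0772 and 0.187 without CERK1_WT replicate 1 and 2 and of 0.0754 and 0.186 without CERK1_3D replicate 1 and 2, while the log2 change stayed between 0.95 and 1.16. CERK1_3D and CERK1_3E did not differ detectably in CERK1 (log2 difference 0.04, SE 0.11, adjusted p = 0.999), and without CERK1_3E replicate 2 that difference was -0.047.

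In CERK1_3A, ARP9, which encodes an actin-related protein, was the 1 gene called: it fell to 16.6 ± 1.0 CPM from 37.9 ± 1.5 in CERK1_WT (log2 -1.19, SE 0.09, adjusted p = 0.0300, lower in 2 of 2 libraries). Of 21274 genes tested by edgeR, 0 rose and 1 fell, 654 had an unadjusted p under 0.05 where chance gives 1064, and DESeq2 called 15. A number below that of chance does not show that lines are alike, and genes not called were not shown to be unchanged. HSC70-1, a cytosolic heat shock cognate protein named after its values were seen, stood at 312 ± 1.7 CPM against 2848 ± 250 in CERK1_WT and was not called (log2 -3.19, SE 0.37, adjusted p = 0.168, lower in 2 of 2 libraries). ARP9 was no longer called without CERK1_WT replicate 2 (adjusted p = 0.0773), CERK1_3A replicate 1 (0.0947) or CERK1_3A replicate 2 (0.0556). It was also lost without either CERK1_3E library, when 2 other genes were called. The count was 9 and 7 without CERK1_WT replicate 1 and 2, 4 and 13 without CERK1_3A replicate 1 and 2, 3 without either CERK1_3D library and 2 without either CERK1_3E library.

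In CERK1_3D, 4 genes rose and 2 fell. The libraries of this line were at least 2-fold apart for 750 genes, against 355 to 388 in the other lines. TWD1, an immunophilin that acts in auxin transport and lies next to CERK1 in the genome, rose to 157 ± 35 CPM from 22.2 ± 2.8 (7.06-fold, log2 2.82, SE 0.19, adjusted p = 0.00577, higher in 2 of 2). The plastid gene ATCG00340, for a photosystem I protein, rose by 1.17 (SE 0.11, adjusted p = 0.0418), and the unannotated locus newGene_80 fell by 2.80 (SE 0.29, adjusted p = 0.0451), both in 2 of 2 libraries. Plastid genes together took 0.191% and 0.323% of counts in the CERK1_3D libraries against 0.0928% and 0.117% in those of CERK1_WT, so the rise of ATCG00340 may reflect plastid reads as a whole. AT1G58936 rose from 0.137 to 4.04 CPM (log2 4.84, SE 0.42, adjusted p = 0.0247, 2 of 2 libraries). It lay below the expression limit of the naming rule and was named after its values were seen. By edgeR 611 genes had an unadjusted p under 0.05, fewer than the 1064 of chance, and DESeq2 called 26, the 6 among them. The call of TWD1 held without each of the 4 libraries compared, whereas the calls of CERK1, ATCG00340, AT1G58936 and newGene_80 were lost without each of them, with adjusted p values from 0.0669 to 0.187. CERK1 and ATCG00340 were lost with the replicate block and without any single library of the other lines too, AT1G58936 without CERK1_3A replicate 2 or either CERK1_3E library, and newGene_80 without either CERK1_3E library. With only the 4 libraries compared all 4 of these were lost, at a mean CPM of at least 5 CERK1, ATCG00340 and newGene_80, and without organelle genes CERK1 and newGene_80. The count was 11 and 10 without CERK1_WT replicate 1 and 2, 12 and 3 without CERK1_3D replicate 1 and 2, and 4 without either CERK1_3E library.

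In CERK1_3E, TWD1 was the 1 gene called and rose to 234 ± 42 CPM from 22.2 ± 2.8 (10.5-fold, log2 3.40, SE 0.20, adjusted p = 0.00331, higher in 2 of 2 libraries). The pathogenesis-related genes PR5 and PR1, markers of salicylic acid signalling, were at 51.3 ± 11 and 41.8 ± 9.8 CPM against 15.2 ± 2.8 and 11.8 ± 6.1 in CERK1_WT and were not called (log2 1.75, SE 0.24, adjusted p = 0.269, and 1.82, SE 0.32, adjusted p = 0.564, both higher in 2 of 2 libraries). The cytochrome P450 gene CYP706A1, named after its values were seen, was at 96.0 ± 1.6 against 37.6 ± 2.1 CPM (adjusted p = 0.0592). By edgeR 0 genes fell, 716 had an unadjusted p under 0.05 and DESeq2 called 37. The call of TWD1 held without each library. The count was 8 and 9 without CERK1_WT replicate 1 and 2, 9 and 3 without CERK1_3E replicate 1 and 2, and 2 without either CERK1_3D library.

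**Figure D3:**
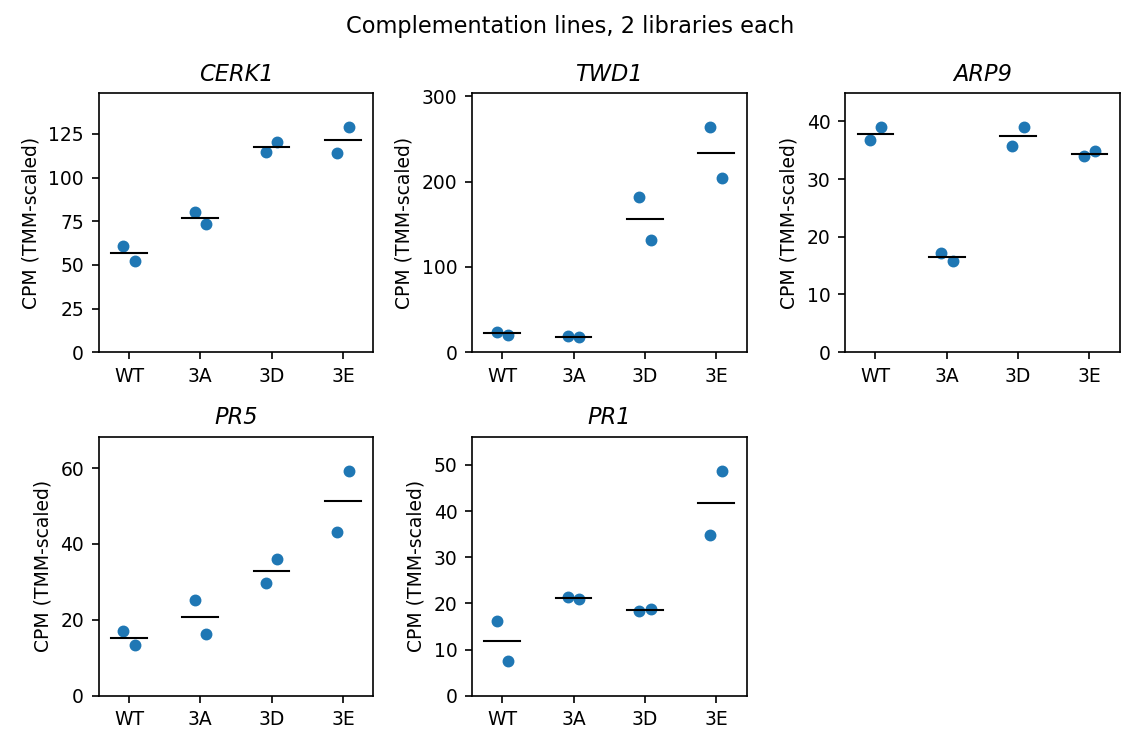
Each point is the TMM-scaled CPM of 1 library of a complementation line and each bar the mean of 2 libraries, for CERK1, TWD1, ARP9, PR5 and PR1. TWD1 is at 157 and 234 CPM in the 3D and 3E lines against 22.2 in CERK1_WT.

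To ask whether the mutated forms shifted untreated seedlings toward the flg22 response, the 1156 measured flg22-raised genes of wild type were tested as a set. Their median log2 difference from CERK1_WT was 0.04 in CERK1_3A, 0.08 in CERK1_3D and 0.13 in CERK1_3E, and 676, 745 and 810 of them lay above 0. Camera at the preset correlation gave p = 0.0370, 3.46e-05 and 2.86e-09. With an estimated correlation the values were p = 0.447, 0.169 and 0.0743, and by fry p = 0.525, 0.268 and 0.125, so no shift was called by either. By camera at the preset correlation, the CERK1_3A call was lost without CERK1_3A replicate 1 (p = 0.444) and changed direction without CERK1_WT replicate 2 (p = 0.393), and the CERK1_3D call was lost without CERK1_WT replicate 2 (p = 0.501) or CERK1_3D replicate 1 (p = 0.110). The 87 flg22-lowered genes had medians of -0.05 (camera p = 0.339), 0.05 (p = 0.0126, upward, and p = 0.113 with an estimated correlation) and -0.07 (p = 0.0941). By camera at the preset correlation, the CERK1_3D call of this set was lost without CERK1_3D replicate 2 (p = 0.188) and CERK1_WT replicate 2 (p = 0.0557), and without CERK1_3E replicate 1 the CERK1_3E set passed (p = 0.0126).

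Among the fixed lists, several of immunity and hormone genes lay above CERK1_WT in all 3 variant lines by camera, and none of these calls held with an estimated correlation. The 3 comparisons share the 2 CERK1_WT libraries, so lists can move alike by chance in those controls, and no value without change was computed for lists. Jasmonate genes had medians of 0.12, 0.47 and 0.20 in CERK1_3A, CERK1_3D and CERK1_3E with 20, 27 and 20 of 27 members above 0 (adjusted p = 0.0162, 1.34e-16 and 0.0198, and adjusted p = 0.725, 0.277 and 0.642 with an estimated correlation). In CERK1_3D TAT3, a jasmonate-responsive aminotransferase, was at 98.1 ± 44 against 20.7 ± 2.1 CPM (log2 2.25, SE 0.36, adjusted p = 0.436 over all genes and higher in 2 of 2 libraries). Salicylic acid genes had medians of 0.26, 0.33 and 0.34 in CERK1_3A, CERK1_3D and CERK1_3E with 26, 28 and 25 of 32 above 0 (adjusted p = 0.000119, 1.23e-09 and 1.45e-09, and adjusted p = 0.665, 0.376 and 0.305 with an estimated correlation). Immediate early genes had a median of 0.60 in CERK1_3E with 26 of 30 above 0 (adjusted p = 3.03e-06, and adjusted p = 0.177 with an estimated correlation) and 0.33 in CERK1_3D (adjusted p = 0.000306, and adjusted p = 0.277 with an estimated correlation), and were not called in CERK1_3A (median 0.01, adjusted p = 0.192). Iron deficiency genes, which include the uptake regulator bHLH39, lay below CERK1_WT in all 3, with medians of -0.21, -0.24 and -0.61 and 4, 3 and 2 of 18 above 0 (adjusted p = 0.000493, 0.000199 and 9.77e-10, and adjusted p = 0.326, 0.277 and 0.119 with an estimated correlation). Heat shock genes had medians of -0.28, 0.51 and -0.25 in the 3 variants (adjusted p = 0.00308, 9.18e-06 and 0.0414, and adjusted p = 0.716, 0.394 and 0.642 with an estimated correlation). Camera called 10, 9 and 13 of 18 lists in CERK1_3A, CERK1_3D and CERK1_3E, 7, 7 and 8 of them upward, and 0 were called with an estimated correlation, where the lowest adjusted p values were 0.326, 0.277 and 0.119, or by fry's test of a common direction. Its test of changes in either direction called 0, 1 and 0. Adjusted over the list alone, 3 salicylic acid genes (PBS3, BGL2, PR5), TAT3 and the endoplasmic reticulum chaperone BIP3 rose in CERK1_3D, 3 salicylic acid genes (PR1, PR5, CBP60G) and the auxin-conjugating enzyme gene DFL1 rose and bHLH39 fell in CERK1_3E, and 0 changed in CERK1_3A. BGL2 was named after its values were seen.

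Between the variants, TWD1 was higher in both CERK1_3D and CERK1_3E than in CERK1_3A. It rose by 3.09 (SE 0.19, adjusted p = 0.00316) and 3.67 (SE 0.20, adjusted p = 0.00204), each in 2 of 2 libraries, and ARP9 rose by 1.17 (adjusted p = 0.0114) and 1.05 (adjusted p = 0.0382), SE 0.09 in both. The locus newGene_80 was at 1059 ± 31 CPM in CERK1_3E and 61.7 ± 21 in CERK1_3D (log2 4.1, SE 0.31, adjusted p = 0.0123, 2 of 2 libraries). AT1G58936, named after its values were seen, differed between CERK1_3D and CERK1_3A (log2 4.04, SE 0.40, adjusted p = 0.0354) and between CERK1_3E and CERK1_3D (log2 -4.62, SE 0.42, adjusted p = 0.0319). AT2G01021, which lies beside ribosomal RNA genes, had 1 count in each CERK1_3A library and 124716 and 23468 in the CERK1_3D libraries (adjusted p = 0.0293). By edgeR, 4 genes rose and 1 fell in CERK1_3D against CERK1_3A (1230 at an unadjusted p under 0.05, 75 by DESeq2), 2 rose and 0 fell in CERK1_3E against CERK1_3A (521 and 31), and 2 rose and 1 fell in CERK1_3E against CERK1_3D (858 and 40). Adjusted over the list alone, 6 heat shock genes and 1 jasmonate gene were higher in CERK1_3D than in CERK1_3A, 1 salicylic acid gene was higher in CERK1_3E than in CERK1_3A, and 3 jasmonate genes and 1 heat shock gene were lower in CERK1_3E than in CERK1_3D. Camera called 5, 4 and 10 lists in the 3 comparisons and 0 with an estimated correlation, where the lowest adjusted p values were 0.194, 0.385 and 0.380. TWD1 in CERK1_3D was lost without CERK1_3A replicate 1 (adjusted p = 0.0595). ARP9 was lost without either CERK1_3A library (0.0746 and 0.0724 in CERK1_3D, 0.120 and 0.0965 in CERK1_3E), in CERK1_3E without replicate 1 or 2 of that line (0.108 and 0.109), and in both without either CERK1_WT library, when 2 genes were called in each comparison. AT1G58936 was lost in both comparisons without any 1 of the 8 libraries (0.0634 to 0.267 without those compared), and AT2G01021 without either CERK1_3A library (0.290 and 0.216) or either CERK1_WT library. With the replicate block ARP9 was lost in CERK1_3E, AT1G58936 in both comparisons and AT2G01021 in CERK1_3D. With only the 4 libraries compared ARP9 was lost in CERK1_3D, AT1G58936 in both comparisons and AT2G01021 in CERK1_3D. Between CERK1_3D and CERK1_3A the count was 9 without CERK1_3A replicate 2 and 16 and 8 without CERK1_3D replicate 1 and 2. Between CERK1_3E and CERK1_3A it was 6 and 15 without CERK1_3A replicate 1 and 2, 9 and 6 without CERK1_3E replicate 1 and 2, and 6 without either CERK1_3D library. Between CERK1_3E and CERK1_3D it was 11 and 7 without CERK1_3D replicate 1 and 2 and 11 and 6 without CERK1_3E replicate 1 and 2.

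CERK1_3D and CERK1_3E were compared with the same 2 CERK1_WT libraries, so their fold changes share the error of those controls. Of 6 and 1 calls, 1 was shared, the rise of TWD1, where independent draws give 0.000188 and simulated unchanged groups against the same controls gave 0.15 on average over 20 simulations. Across 13312 genes their covariance was 0.0235 against 0.0224 in the simulated groups, r was 0.40 against 0.49, and 62.7% of genes had the same sign against 66.7%, so these measures did not point one way. CERK1_3A shared the controls as well: with CERK1_3E the values were 0.0293 against 0.0225, r of 0.47 against 0.49 and 67.7% against 66.6%, and with CERK1_3D 0.0211 against 0.0225, r of 0.36 against 0.49 and 56.8% against 66.5%. The 2 controls were not split between the variants, so the shared part of the error was not removed.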

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

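All tests of explanations in this part were chosen after the results they address had been seen.

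TWD1 rose in CERK1_3D and CERK1_3E and not detectably in CERK1_3A, and it lies next to CERK1. AT3G21620 and AT3G21650, on either side of CERK1 and TWD1, argue against a change of the region that takes them in. Their largest log2 fold change in the 2 lines was -0.021. They cannot speak to a change confined to CERK1 and TWD1, such as reads shared between these genes, which was not tested and stays open. A shared construct that carries TWD1 transcript along with CERK1 would have placed CERK1_3A on the line through CERK1_WT and CERK1_3D, but the higher of its 2 libraries had 0.304 times the TWD1 level of that line. This value reuses the TWD1 levels that raised the question and a CERK1 difference in CERK1_3A that was not called. It bears only on a construct acting alike in every line and cannot decide whether TWD1 transcript came from the construct. Signalling of the kind flg22 starts cannot be told apart: the highest upper bound of the flg22 ratio of TWD1 was 1.42, but it covers counting error between single libraries alone and the duration of treatment is not known. Differences between the construct or insertion in single lines, and an effect of the 3D and 3E forms themselves, stay open as hypotheses, since construct and line were not separated.

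Root-expressed genes were lower in cerk1_mock than in WT_mock, and 9 of the 60 measured named genes moved at least 2-fold down with flg22 in wild type and at least 2-fold up in cerk1, a difference that was not tested for want of replicates. The rule for named genes picked large falls and large differences of response, so this share is not a rate. Over all 18872 genes, 36 moved in this way. Lower depth could not account for the low root-expressed genes, since the total of cerk1_mock was 0.978 times that of WT_mock. Less root tissue in that sample cannot be told apart from other causes: root-hair markers differed from endodermis markers by -1.34 in median log2 ratio, but the members of both overlapped, from -2.65 to -1.09 and from -1.22 to -0.16. The 3 meristem markers, outside that test, had a median of -0.39 and lay from -0.68 to -0.12, above the root-hair range. These values come from single libraries, so the uneven falls do not decide the question. Nor do they show which mock library was unusual. Root markers had a median of -0.48 in WT_flg22 against WT_mock and of 0.30 in cerk1_flg22 against cerk1_mock. Between the flg22 libraries their median was -0.14, so a high WT_mock library was not separated from a low cerk1_mock library. The opposite responses rest on the same mock libraries. The cerk1 genotype cannot be told apart either, because root-hair markers had a median of -0.37 between the flg22 libraries, flg22 itself may change these genes, and each combination had 1 library. Of the 9 named genes, AT3G22142, HRGP1, BGLU34 and BGLU35 were 4.14-, 4.79-, 4.39- and 3.84-fold lower in cerk1_flg22 than in WT_flg22. AT1G52070, AT1G52060, AT3G19430 and AT5G54370 were higher there, and SHV2 was at 0.879 times.

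The differences of response, cerk1 minus wild type on the log2 scale, were 7.21 for AT1G52070, 6.62 for AT1G52060, 5.73 for AT3G19430, 5.45 for AT5G54370, 4.1 for AT3G22142, 3.04 for BGLU34, 3.00 for HRGP1, 2.95 for BGLU35 and 2.51 for the root-hair gene SHV2. In all genes measured, 36 moved in opposite directions by at least 2-fold each way, and all 36 were lower in wild type and higher in cerk1. Between CERK1_3E and CERK1_3D, AT1G58936 differed by -4.62 and newGene_80 by 4.1, both tested by edgeR.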

How the results depend on the processing

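The direct comparison of the 2 flg22 libraries and the count without genes lowered by flg22 were chosen after seeing the data, and all other settings in this part were planned. The counts of called genes between lines rested on the tool and on single libraries, and where a value moved the cause was not tested. RLE and upper-quartile factors and a log2 change of at least 1 left all 6 counts within 1.5 times of the value given. DESeq2 called 15 genes in CERK1_3A, 26 in CERK1_3D and 37 in CERK1_3E against CERK1_WT, 75 between CERK1_3D and CERK1_3A, 31 between CERK1_3E and CERK1_3A and 40 between CERK1_3E and CERK1_3D, with every edgeR call among them. Without a low-count filter there were 2 in CERK1_3A, 3 in CERK1_3E and 5 between CERK1_3E and CERK1_3A. With only the 4 libraries compared there were 5, 4 and 8, and 5 between CERK1_3E and CERK1_3D. With the replicate block there were 2 in CERK1_3A, 3 between CERK1_3D and CERK1_3A, 1 between CERK1_3E and CERK1_3A and 2 between CERK1_3E and CERK1_3D. In CERK1_3D a mean CPM of at least 5 gave 2, leaving out organelle genes gave 3, the replicate block gave 5 and the 4 libraries compared alone gave 6, and CERK1 was among the calls lost in each of these 4 settings. Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave 2 to 13 in CERK1_3A, 3 to 12 in CERK1_3D, 1 to 9 in CERK1_3E, 2 to 16 between CERK1_3D and CERK1_3A, 2 to 15 between CERK1_3E and CERK1_3A and 3 to 11 between CERK1_3E and CERK1_3D. Among single genes the log2 difference of CERK1 between CERK1_3E and CERK1_3D reversed, from -0.047 to 0.13 over the libraries left out. Of the other pairings of a named gene with a setting, 42 lost a call, 3 gained one and 115 stayed on the same side.

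The flg22-raised set in CERK1_3A lost its call with an estimated correlation (p = 0.447), by fry (0.525), with a 2-fold set (0.296), at a mean CPM of at least 5 (0.191) and with the replicate block (0.0515), and it turned downward without CERK1_WT replicate 2 (0.393). Over the libraries left out its p ran from 1.69e-05 to 0.444. In CERK1_3D p was 0.169 with an estimated correlation and 0.268 by fry, and ran from 8.00e-09 to 0.501 over the libraries left out. In CERK1_3E the values were 0.0743, 0.125 and from 9.15e-14 to 0.0203, so no single library ended that call. With an estimated correlation 0 lists were called in each of the 6 comparisons.

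In the flg22 experiment, a 2-fold size gave 3592 genes in wild type, 3886 in cerk1, 813 between the mock libraries and 892 for the difference of responses. Ratios of CPM + 5 gave 862 in cerk1, 31 between the mock libraries and 24 for the difference of responses, and ratios of CPM + 0.1 gave 351 and 407 for the last 2, since a smaller added value lets more genes of low count pass. Compared directly, the 2 flg22 libraries differed for 24 genes, and without the genes at least 4-fold lower with flg22 in wild type the mock libraries differed for 98. Scalings and filters other than these left the counts of this experiment within 1.5 times. Depth limits the genes of low count, where 3 counts correspond to about 0.151 CPM in WT_mock, and single libraries leave the variation between seedlings unmeasured.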

Other observations

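No test in this part was run beyond the planned ones, and its genes were chosen after their values were seen, apart from CERK1, PIN2, HEI10 and AT2G01021, which the rule for named genes gave in the same experiment.

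Some jasmonate-related genes and PR1 stood higher in cerk1_flg22 than in WT_flg22, in single libraries. The jasmonate-responsive aminotransferase gene TAT3 had 6.06 CPM in WT_flg22 and 33.8 CPM in cerk1_flg22 (5.58-fold, counting interval 4.59 to 6.83), and PDF1.2c, a defensin, 0.25 and 8.56 CPM (34.2-fold, 14.4 to 107). PR1 had 4 counts in WT_flg22 and 157 in cerk1_flg22 (39.5-fold, 15.1 to 147). PR5, another pathogenesis-related gene, was lower in cerk1_flg22 (0.335 times, 0.291 to 0.385), and over the salicylic acid list 2 of 30 genes were at least 2-fold higher and 1 lower, with a median of -0.15 that lay below those of random lists. Over the whole jasmonate list 8 of 25 genes were at least 2-fold higher in cerk1_flg22 than in WT_flg22 and 0 lower, with a median of 0.14. The transporter gene PIN2 (EIR1 in the annotation) went from 29.7 to 10.6 CPM with flg22 in wild type and from 11.9 to 20.7 CPM in cerk1.

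The gene on the other side of CERK1, AT3G21620, was at 2.26 and 2.77 CPM in the 2 cerk1 libraries and at 0.454 and 0.150 CPM in the wild-type libraries, so both libraries titled cerk1 differed from wild type at this locus and at HEI10, whatever the conflicting genotype label of one of them. In the lines AT3G21620 was at 5.43 ± 0.27 CPM in CERK1_WT, 4.67 ± 0.71 in CERK1_3A, 4.49 ± 0.55 in CERK1_3D and 3.89 ± 0.093 in CERK1_3E.

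AT2G01021, beside ribosomal RNA genes, took 0.0393% and 0.0652% of counts in CERK1_WT, 0.346% and 0.0621% in CERK1_3D, 0.0244% and 0.0686% in CERK1_3E, and 1 count in each CERK1_3A library. The gene MLP28, of the major latex protein family, was at 230 ± 15 CPM in CERK1_WT, 128 ± 20 in CERK1_3A, 108 ± 6.2 in CERK1_3D and 120 ± 2.7 in CERK1_3E, lower in 2 of 2 libraries of each variant and called in none (adjusted p = 0.367, 0.0576 and 0.177).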
